A study of Trypanosoma brucei with 16 samples.

How the data were processed

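The series holds 16 poly(A)-enriched RNA libraries of Trypanosoma brucei Lister 427 bloodstream forms: 4 untreated controls and 4 each after 4 hours with PhenDC3, CX-5461 or BMH-21 at 2 times the EC50. Per the labels' protocols, RNA was extracted with the RNeasy Mini Kit and libraries were prepared with the NEB mRNA polyA kit. The authors deposited 1 table of read counts per feature and library; the submitters' processing notes list FastQC, fastp, Bowtie2, SAMtools, featureCounts and Subread 1.5.2, with no parameters. Per the file headers, each feature comes with its contig, start, end, strand and length, and the contig names end in Tb427v10, the assembly used here for all positions. The notes do not state the strand setting or how reads that map to several places were counted, so features with near-identical copies are reported as uncertain. Lengths are multiples of 3 for 98.5% of features, so most are coding lengths; those of the repeated block parts, 169, 2251 and 4322 bp at the median, are not.

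The table holds 17243 features, 5283 of them marked as pseudogenes, on 11 core contigs, 13 expression site contigs, 33 subtelomere arm contigs and 255 unitigs. Its identifiers are not paired with gene names. The reference gene table at hand, for the TREU927 assembly, has 10221 genes, and 0 of the identifiers matched it. Gene lists defined by annotation text, cell type marker lists and named gene families could therefore not be formed, and with no genome sequence no list of quadruplex motifs was made. At most 2 identifiers that rose and 2 that fell are printed for each compound against control; the parts of the naming rule that need annotation could not be applied, and its part on list members was left out to stay within that number.

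Counts were analysed with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr with the 4 groups (10779 kept), libraries were scaled with TMM factors (0.955 to 1.029), and a quasi-likelihood model with the 4 group means was fitted to all 16 libraries (glmQLFit, prior not robust). The 6 pairs of groups were tested with glmQLFTest, with Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a single feature comes from this test. The estimated biological coefficient of variation was 5.6%. The standard error of a log2 fold change was taken as its size over the square root of F. CPM values use the TMM-scaled library sizes, and shares use total counts.

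Lists were tested with camera of limma 3.58.1 on log-CPM (prior count 2), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 6 lists formed from coordinates. These were the expression site contigs; the subtelomere arms and unitigs; the first 3 features (start proximal) and the last 3 features (end proximal) of runs of at least 5 on one strand that begin at a divergent strand switch (530 runs); and the longest and shortest 10% of features (at least 2481 bp and at most 381 bp). Features were named by a fixed rule: adjusted p under 0.05, a mean of at least 10 CPM over the 8 libraries compared, and all 4 libraries of one group on one side of the other 4; the 2 largest rises and 2 largest falls were taken. The groups, lists, tests and this rule were set before the data were examined. The accounts of BES1 before its last feature, of the last feature, of the other expression sites and of the repeated blocks, with their shares of counts, were chosen after seeing the data. Blocks were found from 169 bp, the most frequent length among features off the expression sites that fell at least 4-fold with BMH-21, and its same-strand neighbours within 1000 bp.

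Shares of counts were compared by exact two-sided permutation tests, whose smallest p for 4 against 4 libraries is 0.0286, adjusted over 12 tests. Rank correlations across features used two-sided tests with 100000 permutations. The overlap between compounds was set beside 20 simulations of unchanged groups, independent lists, and the controls split 2 and 2 in 6 ways. The fit was tested on simulated data for BMH-21 against control with 200 changed features among 10739: it recovered 56% of those changed 1.25-fold, 89.8% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 16 unchanged features were called, 8.6% of the calls. Alternatives were RLE factors, library size only, other filters, a robust prior, a replicate block, only the 8 libraries compared, DESeq2 1.42.0, camera with an estimated correlation, fry, stricter thresholds and leaving out each replicate; TMM factors without the expression sites and lists on core contigs alone were added after seeing the data. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. All columns were used, and no library was left out.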

Results

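Poly(A)-enriched RNA was sequenced from Trypanosoma brucei Lister 427 bloodstream forms, the stage that lives in mammalian blood, after 4 hours with PhenDC3, CX-5461 or BMH-21 or without compound. Each compound was given at 2 times its EC50. PhenDC3 binds G-quadruplexes, folded structures of guanine-rich nucleic acid. CX-5461 and BMH-21 are known as inhibitors of RNA polymerase I, which in this parasite transcribes ribosomal RNA and the active expression site of the variant surface glycoprotein, the coat protein. Whether CX-5461 or BMH-21 also binds G-quadruplexes was not measured here, so the compounds cannot be divided by that trait. Each of the 4 groups held 4 libraries, labelled biological replicates. Total counts per library ranged from 17.26 M to 22.88 M. The group means were 19.12 ± 0.69 M in control, 19.08 ± 2.19 M with BMH-21, 20.63 ± 1.74 M with CX-5461 and 20.98 ± 1.29 M with PhenDC3 (SD, n = 4 each). Of 17243 features in the count table, 10779 had counts high enough to test. The table gives no gene names, so features are described by their contig and position on the Tb427v10 assembly, as the table gives them. The first principal component of log counts held 47.8% of the variance and the second 17.1%, and the 4 libraries of each group lay together on both. The comparisons with control ask which transcripts each compound changed, in a series whose title concerns G-quadruplexes in coding regions and at transcription start sites.

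After BMH-21, transcripts of the expression site contigs and of a family of repeated blocks fell steeply, while most other transcripts moved little. The contig BES1 held 89.4% of the control counts on the 13 expression site contigs. All 17 of its tested features before the last fell, with a median log2 fold change of -2.60 and a range from -4.11 to -1.19. Together they took 1.48% ± 0.0593 of the counts in control libraries and 0.396% ± 0.0119 after BMH-21 (SD, n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.0312 over 12 share tests), lower in 4 of 4 libraries. The last feature of BES1, 1431 bp long at 75570 to 77000 and chosen after its values were seen, fell by only 0.57 ± 0.06 on the log2 scale (SE).

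Up to the last feature of BES1, the fall with BMH-21 deepened with distance from the start of the contig. The feature at 22246 to 23408 had a log2 fold change of -1.56 ± 0.05 (SE), the one at 50270 to 54076 one of -3.03 ± 0.06, and the one at 66394 to 67383 one of -3.96 ± 0.06. Position and fold change had a Spearman rank correlation of -0.60 across all 18 features (two-sided permutation p = 0.0102), although features on one contig are not independent replicates. It was -0.90 across the 17 before the last, which were set apart after the values were seen. The feature at 40387 to 41124 departed from this order with the smallest fall, -1.19 ± 0.05. The last feature held 8.23% ± 0.148 of control counts and 5.75% ± 0.18 after BMH-21 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0312), lower in 4 of 4 libraries.

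**Figure D1:**
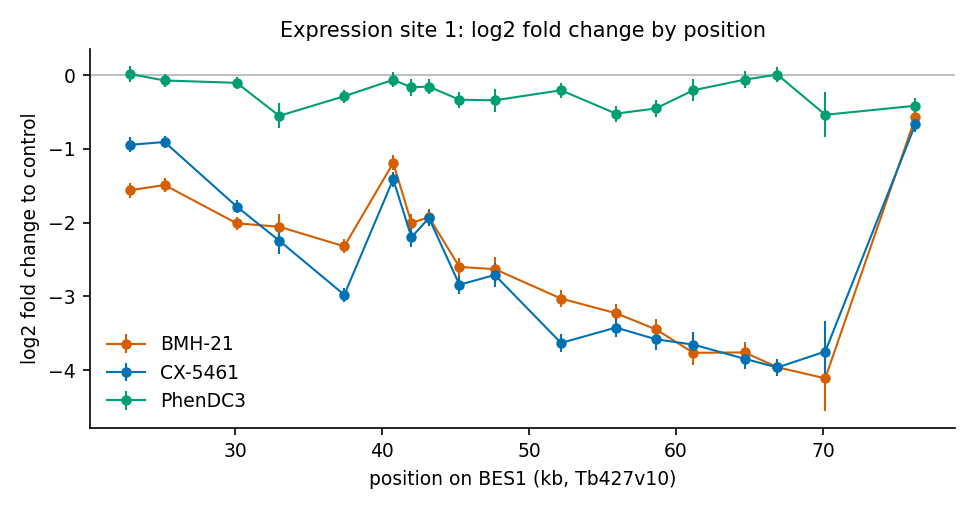
Log2 fold change to control (vertical axis) of the 18 tested features of BES1 against the middle of each feature in kb on Tb427v10 (horizontal axis), for BMH-21, CX-5461 and PhenDC3, with bars of 2 standard errors and n = 4 libraries per group. With BMH-21 the features before the last run from -1.19 to -4.11 and the last lies at -0.57.

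On the other 12 expression site contigs, 100 of 135 tested features fell with BMH-21 and 5 rose, with a median log2 fold change of -1.47. Over all expression site contigs, 118 of 153 tested features fell and 5 rose (122 and 6 adjusted over the list alone). The camera test against all other features gave an adjusted p of 1.55e-82. With an estimated correlation it held at 6.76e-06, the highest over 13 camera alternatives (lowest 1.15e-97). Expression sites hold near-identical genes, so values of single features on these 12 contigs are uncertain. Of the 5 rises, 4 were of features 1158 to 1206 bp long on BES11 and BES13, chosen after their values were seen. At 13901 to 15062 of BES11 the mean rose from 9.66 to 24.5 CPM (log2 fold change 1.34 ± 0.12, SE, n = 4 libraries per group, edgeR adjusted p = 2.82e-10).

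The repeated blocks, a set defined after the data were seen, consisted of a first part of about 2251 bp, a middle part of 169 bp and, as the third part, one of about 4322 bp, all on one strand. There were 21 blocks, 18 of them with all 3 parts, on 18 contigs: 4 core contigs, 12 unitigs and 2 subtelomere arms. All 60 features of the blocks fell with BMH-21. The median log2 fold change was -2.34 for the first part, -4.67 for the middle part and -3.07 for the third part. Their summed share went from 0.847% ± 0.0483 of control counts to 0.128% ± 0.0421 (SD, n = 4 each), with BMH-21 replicate 1 at 0.19% and the others between 0.0955% and 0.115%. No p-value is given for this fall, because the blocks were found from features that fell with BMH-21. The copies resemble one another in length, so the counts of a single copy are uncertain. The steepest falls under the naming rule were middle parts of such blocks. Tb427_070076100 on Chr7_core at 1951297 to 1951465 went from 50.7 ± 3.43 to 0.996 ± 0.224 CPM (SD, n = 4 each, log2 fold change -5.64 ± 0.13, SE, adjusted p = 1.01e-25). Tb427_000666300 on unitig_1881 at 4352 to 4520 had a log2 fold change of -5.58 ± 0.19 (SE, adjusted p = 2.73e-21).

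**Figure D2:**
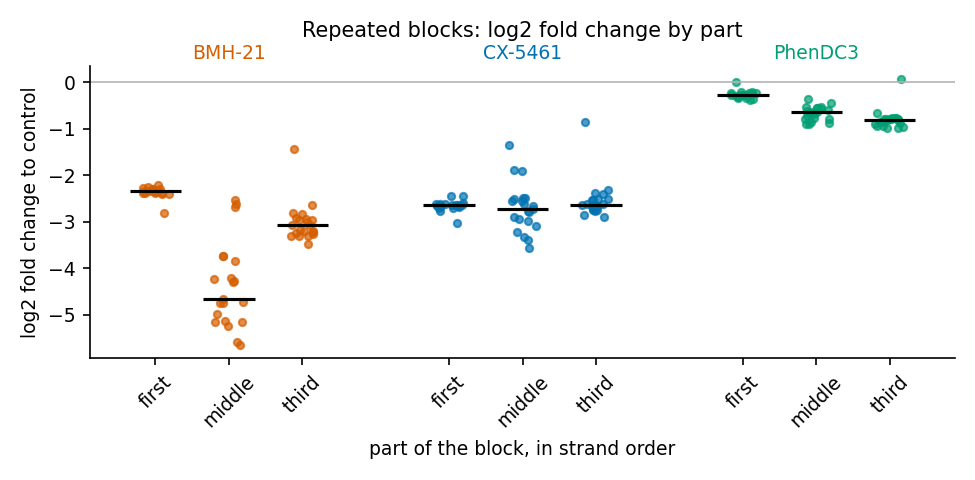
Log2 fold change to control (vertical axis) of each feature of the repeated blocks by its part of the block (horizontal axis) for BMH-21, CX-5461 and PhenDC3; points are features and black lines medians, from n = 4 libraries per group. The middle part has a median of -4.67 with BMH-21 and of -2.73 with CX-5461.

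Rises of at least 2-fold with BMH-21 were fewer than such falls, 16 against 261. Tb427_080054000 on Chr8_core at 1330955 to 1332283 rose from 258 ± 18.4 to 757 ± 39.3 CPM (SD, n = 4 each, log2 fold change 1.55 ± 0.05, SE, adjusted p = 7.79e-22). Tb427_090026000 on Chr9_core at 546098 to 548605 rose from 688 ± 37.5 to 2010 ± 58.1 CPM (log2 fold change 1.55 ± 0.04, SE, adjusted p = 3.65e-23). Both were higher in 4 of 4 libraries. In all, edgeR called 1885 features, 933 higher and 952 lower, and 277 of these by at least 2-fold, of which 261 were lower. Of the 261, 17 lay on BES1, 81 on the other expression site contigs, 60 in the blocks, 48 elsewhere on subtelomere arms, 38 on unitigs and 17 on core contigs. The groups did not overlap for 18.8% of features, against 2.86% by chance.

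Of the features on subtelomere arms and unitigs, 284 of 2097 fell with BMH-21 and 34 rose (269 and 33 adjusted over the list alone), with a median of -0.12 and a camera adjusted p of 1.42e-06. That call did not hold with an estimated correlation (adjusted p = 0.131, the highest over 13 camera alternatives, lowest 2.42e-12). The list includes the repeated blocks on these contigs, which all fell, and it was not tested without them. Transcription start proximal features did not pass, with 83 of 807 lower and 53 higher (81 and 53 adjusted over the list alone), nor did the end proximal features, with 110 of 775 lower and 61 higher (123 and 68 adjusted over the list alone), though with library size only their camera adjusted p was 0.0117. Fry, which tests a list against no change and not against other features, called the end proximal features lower (adjusted p = 0.00131). Of long features, 142 of 1637 were lower and 124 higher (138 and 121 adjusted over the list alone), and of short features, 63 of 1165 were lower and 100 higher (58 and 93 adjusted over the list alone). The camera adjusted p-values of these 4 lists were 0.622, 0.145, 0.606 and 0.238, and the short list had a median of 0.03 but a mean of -0.09.

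CX-5461 lowered the same regions. All 17 features of BES1 before the last fell, with a median log2 fold change of -2.84 and a range from -3.96 to -0.91. Their share of counts went from 1.48% ± 0.0593 to 0.531% ± 0.0168 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0312), lower in 4 of 4 libraries. The fall again deepened along the contig up to the last feature (Spearman -0.61 across all 18 features, permutation p = 0.00815, and -0.91 across the 17), from -0.95 ± 0.05 (SE) at 22246 to -3.96 ± 0.06 at 66394. The last feature fell by 0.67 ± 0.06 (SE), and its share went from 8.23% ± 0.148 to 5.52% ± 0.273 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0312), lower in 4 of 4 libraries. All repeated block parts fell by like amounts, with medians of -2.65, -2.73 and -2.64 for the first, the middle and the third part, and 59 of the 60 features were called lower.

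On the other 12 expression site contigs, 113 of 135 features fell with CX-5461 and 2 rose, with a median of -1.51. Over all expression site contigs, 131 of 153 fell and 2 rose (135 and 2 adjusted over the list alone), with a camera adjusted p of 3.13e-66. With an estimated correlation it held at 2.2e-05, the highest over 13 camera alternatives (lowest 2.75e-85). The summed share of the blocks went from 0.847% ± 0.0483 to 0.145% ± 0.00946 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0312), lower in 4 of 4 libraries. The blocks were found from falls with BMH-21 against these same controls, which this p-value does not allow for. The steepest fall under the naming rule was that of Tb427_080005100, marked as a pseudogene on Chr8_core at 4257 to 5074, from 22.0 ± 2.66 to 0.617 ± 0.0432 CPM (SD, n = 4 each, log2 fold change -5.14 ± 0.19, SE, adjusted p = 4.78e-20). It fell less with BMH-21, by 1.58 on the log2 scale. Next came Tb427_000015800 on BES1 at 66394 to 67383, which went from 725 ± 23.9 to 46.4 ± 4.28 CPM (log2 fold change -3.96 ± 0.06, SE, adjusted p = 2.71e-30).

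Tb427_090026000, which rose with BMH-21, also rose with CX-5461, to 1547 ± 35.7 CPM (SD, n = 4, log2 fold change 1.17 ± 0.04, SE, adjusted p = 4.63e-20). Tb427_100015200 on Chr10_core at 257780 to 259174 rose from 298 ± 30.2 to 670 ± 44.7 CPM (SD, n = 4 each, log2 fold change 1.17 ± 0.06, SE, adjusted p = 2.85e-16), higher in 4 of 4 libraries. Its rise with BMH-21 was larger (log2 fold change 1.44). With CX-5461 edgeR called 3493 features, 1590 higher and 1903 lower, and 318 by at least 2-fold, of which 295 were lower. Of the 295, 15 lay on BES1, 79 on the other expression site contigs, 59 in the blocks, 54 elsewhere on subtelomere arms, 70 on unitigs and 18 on core contigs. The groups did not overlap for 29.8% of features, against 2.86% by chance.

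Of the features on subtelomere arms and unitigs, 528 of 2097 fell with CX-5461 and 76 rose (512 and 71 adjusted over the list alone), with a median of -0.18 and a camera adjusted p of 9.23e-07. The call did not hold with an estimated correlation (adjusted p = 0.123, the highest over 13 camera alternatives, lowest 1.23e-14). This list again includes the repeated blocks on these contigs and was not tested without them. No other list passed. Of start proximal features 174 of 807 were lower and 74 higher (173 and 72 adjusted over the list alone), with an adjusted p of 0.162, of 0.0234 without control replicate 1 and of 0.0433 with library size only. Of end proximal features 162 of 775 were lower and 108 higher (168 and 112 adjusted over the list alone), with an adjusted p of 0.469. Of long features 366 of 1637 were lower and 226 higher (371 and 233 adjusted over the list alone), with an adjusted p of 0.308. Of short features 102 of 1165 were lower and 187 higher (89 and 168 adjusted over the list alone), with an adjusted p of 0.102, a median of 0.04 and a mean of -0.03. Fry called the start proximal (adjusted p = 0.0242), end proximal (0.00827) and long features (0.0123) lower.

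**Figure D3:**
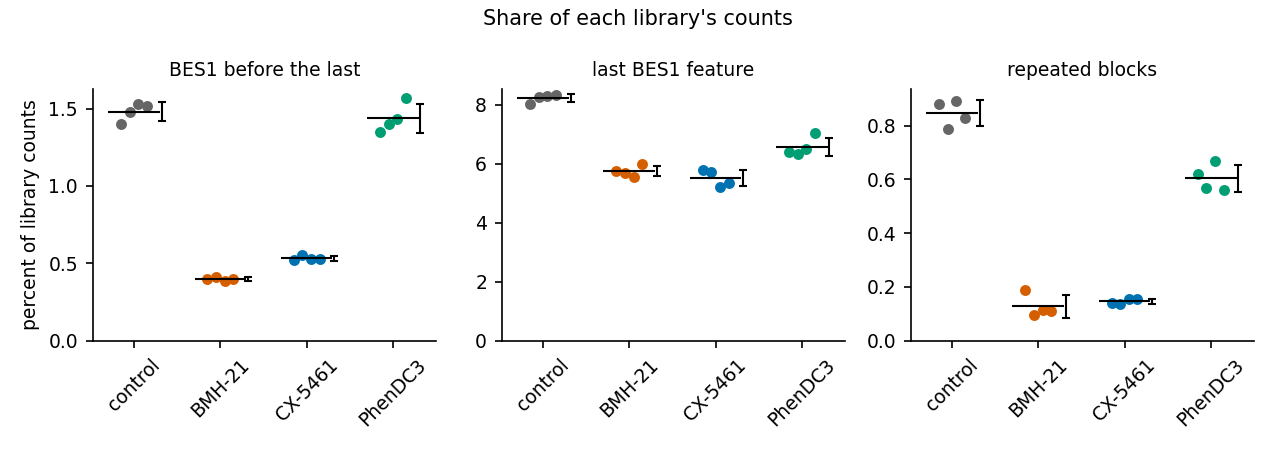
Percent of each library's counts (vertical axes) in the 17 BES1 features before the last, in the last BES1 feature and in the repeated blocks, by group (horizontal axes); points are libraries, lines means and bars SD, n = 4 per group. The last feature took 8.23% of control counts, and 5.75%, 5.52% and 6.57% with BMH-21, CX-5461 and PhenDC3.

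At an adjusted p under 0.05, PhenDC3 changed more transcripts than the other compounds did, in both directions and without the steep fall on BES1. By at least 2-fold it changed fewer, 235 against 277 with BMH-21 and 318 with CX-5461. Of the 17 BES1 features before the last, 12 fell and 5 were not called, with a median of -0.21. No position trend passed the threshold (Spearman -0.30 across all 18 features, permutation p = 0.221). For the share of these 17 features, 1.44% ± 0.0926 beside 1.48% ± 0.0593 in control, no difference was found (SD, n = 4 each, exact permutation p = 0.486, adjusted p = 0.486). The last BES1 feature fell by 0.42 ± 0.06 (SE) and its share went from 8.23% ± 0.148 to 6.57% ± 0.315 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0312), lower in 4 of 4 libraries. In the repeated blocks 51 of 60 features fell, with medians of -0.28, -0.65 and -0.81 for the first, the middle and the third part. The share went from 0.847% ± 0.0483 to 0.603% ± 0.0499 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0312), lower in 4 of 4 libraries. Here too, the p-value does not allow for the choice of blocks against these same controls.

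The largest rises with PhenDC3 under the naming rule were on core contigs. Tb427_100115000 on Chr10_core at 2627658 to 2628620 rose from 63.8 ± 2.11 to 292 ± 6.65 CPM (SD, n = 4 each, log2 fold change 2.20 ± 0.05, SE, adjusted p = 1.36e-25). Tb427_100068600, marked as a pseudogene on Chr10_core at 1620709 to 1621248, rose from 6.62 ± 1.58 to 30.1 ± 2.73 CPM (log2 fold change 2.18 ± 0.13, SE, adjusted p = 1.13e-14). Neither rose with BMH-21 or CX-5461. The largest falls were those of Tb427_110138000 on Chr11_core at 3295299 to 3295952, from 42.0 ± 1.32 to 17.98 ± 1.72 CPM (SD, n = 4 each, log2 fold change -1.23 ± 0.08, SE, adjusted p = 7.95e-14), and of Tb427_110019500 on Chr11_core at 430073 to 434272 (log2 fold change -1.22 ± 0.11, SE, adjusted p = 2.34e-10), and each held in 4 of 4 libraries. Tb427_110019500 also fell with CX-5461 (log2 fold change -1.38) and BMH-21 (-0.78). Tb427_110138000 fell less with CX-5461 (-0.31) and was not called with BMH-21 (0.17). Both features that rose most with BMH-21 fell with PhenDC3, Tb427_080054000 by 0.64 and Tb427_090026000 by 0.71 on the log2 scale.

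With PhenDC3 edgeR called 6117 features, 2983 higher and 3134 lower, with a median absolute log2 fold change of 0.32 among them. Of these, 235 changed by at least 2-fold, 119 higher and 116 lower. Outside the repeated blocks, the rises included 60 of 8515 tested features on core contigs, 34 of 619 on subtelomere arms and 22 of 1432 on unitigs. The falls included 73 of 1432 on unitigs, 22 of 8515 on core contigs and 20 of 619 on arms. Rises and falls of this size thus took a larger share of the arm and unitig features than of the core features. The groups did not overlap for 49.2% of features, against 2.86% by chance. On expression site contigs 50 of 153 features fell and 10 rose (49 and 9 adjusted over the list alone), with a median of -0.12 and a camera adjusted p of 0.0531. That value crossed the threshold under 6 of 13 camera alternatives (0.0147 to 0.638), among them leaving out control replicate 1 or 2 or PhenDC3 replicate 3 or 4. Fry gave an adjusted p of 0.00963.

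The list that the series title points to, transcription start proximal features, showed no shift past the threshold with PhenDC3. Of these, 252 of 807 fell and 152 rose (247 and 150 adjusted over the list alone), with a median of -0.06 and a camera adjusted p of 0.184, and of 0.0472 without control replicate 1. Fry called this list lower (adjusted p = 0.02). End proximal features did not pass either, with 208 of 775 lower and 160 higher (200 and 156 adjusted over the list alone, adjusted p = 0.47). Nor did long features, with 573 of 1637 lower and 497 higher (580 and 504 adjusted over the list alone, adjusted p = 0.643). Short features were lower, with 336 of 1165 lower and 100 higher (308 and 88 adjusted over the list alone, median -0.12, adjusted p = 0.0161). Features of arms and unitigs were lower too, with 608 of 2097 lower and 189 higher (561 and 176 adjusted over the list alone, median -0.18, adjusted p = 0.00483). Neither call held with an estimated correlation (adjusted p = 0.479 for both, the highest over 13 camera alternatives, lowest 0.000758 and 4.82e-06) or with no filter on low counts. The arm and unitig list here too includes repeated blocks and was not tested without them.

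The fold changes of BMH-21 and CX-5461 followed one another far more closely than those of either did with PhenDC3. BMH-21 and CX-5461 shared 564 higher and 670 lower calls, where independent lists of those sizes would share 137.6 and 168.1, and only 34 calls were in opposite directions. Pearson's r of their log2 fold changes across the 10779 features was 0.863, beside 0.503 in 20 simulations of unchanged groups against the same controls. The covariance was 0.187, beside 0.00772 simulated, and r was 0.768 with the controls split 2 and 2. Core contigs alone gave an r of 0.736. Genes are not independent replicates, so these values describe the profiles.

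BMH-21 and PhenDC3 shared 359 higher and 412 lower calls (258.2 and 276.8 for independent lists), while 481 were in opposite directions. The number of opposite calls for independent lists was not computed for any pair, so the 481 are not set against chance. The r of BMH-21 and PhenDC3 was 0.185, with a simulated value of 0.505, a covariance of 0.0338 beside 0.00776, and an r of 0.117 with split controls. CX-5461 and PhenDC3 shared 934 higher and 1217 lower calls (440 and 553.3 for independent lists), with 313 in opposite directions. Their r was 0.323, with a simulated value of 0.515, a covariance of 0.0563 beside 0.00784, and an r of 0.241 with split controls.

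**Figure D4:**
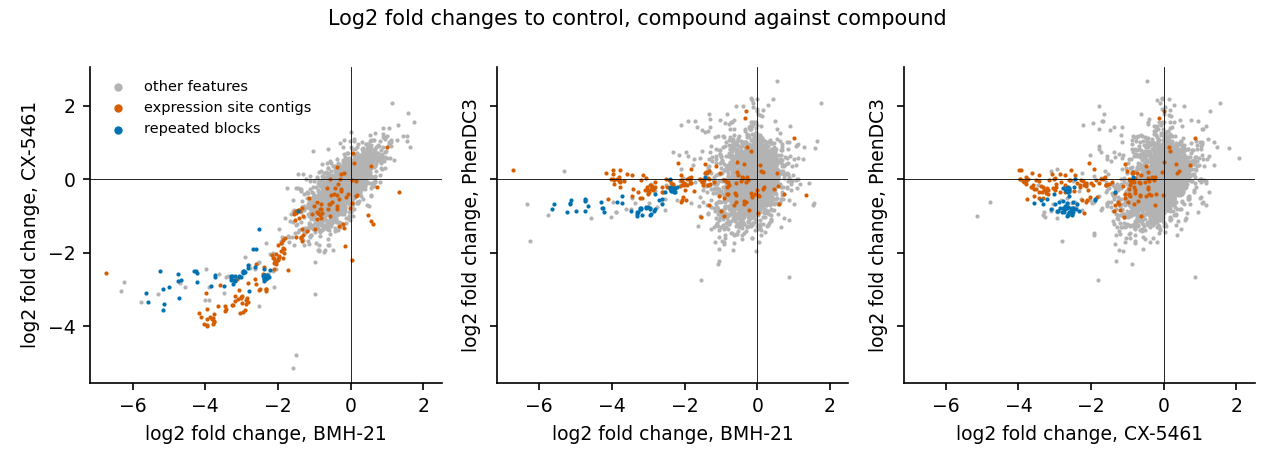
Log2 fold change to control of each of the 10779 tested features for pairs of compounds (both axes, log2 scale); orange points lie on expression site contigs, blue points in repeated blocks and grey points elsewhere, from n = 4 libraries per group. Pearson's r across features is 0.863 for BMH-21 and CX-5461, 0.185 for BMH-21 and PhenDC3 and 0.323 for CX-5461 and PhenDC3.

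Compared directly, CX-5461 and BMH-21 differed in the middle part of the repeated blocks, which was called higher with CX-5461 in 20 of 21 blocks (median log2 difference 1.74). The third part was called higher in 18 of 21 (0.45). The blocks were found from middle parts that fell with BMH-21, so a lower middle part with BMH-21 was partly selected for. The copies may share reads, so they are not independent observations. Over all block features the median difference was 0.48, and 0.71 without BMH-21 replicate 1. On BES1 the feature at 22246 to 23408 was higher with CX-5461 than with BMH-21 by 0.62 ± 0.05 (SE) and the feature at 35523 to 39329 was lower by 0.66 ± 0.05 (SE). Of the 17 features before the last, 3 were higher and 6 lower. The pseudogene on Chr8_core at 4257 to 5074, named above for CX-5461, had 0.617 ± 0.0432 CPM with CX-5461 and 7.33 ± 1.14 CPM with BMH-21 (SD, n = 4 each, log2 difference -3.56, adjusted p = 4.76e-13). The feature at 13901 to 15062 of BES11 had 7.58 ± 0.621 CPM with CX-5461 and 24.5 ± 2.02 CPM with BMH-21 (SD, n = 4 each, log2 difference -1.70 ± 0.12, SE, adjusted p = 2.09e-11). On Chr7_core, the feature at 285241 to 285753 had 21.9 ± 0.305 and 10.5 ± 1.63 CPM (log2 difference 1.06 ± 0.09, SE, adjusted p = 7.9e-10). In all 1889 features differed, 738 higher and 1151 lower with CX-5461, but only 50 by at least 2-fold. No list passed camera (0 of 6, with 1 at an unadjusted p under 0.05, the expression site contigs at 0.0456), and fry called 0. The camera adjusted p-values ran from 0.273 to 0.391, and library size only gave 0.0197 for the expression site contigs and 0.0472 for the arms and unitigs.

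PhenDC3 and BMH-21 differed in 6288 features, 3199 higher and 3089 lower with PhenDC3, and 511 by at least 2-fold, of which 433 were higher. The expression site contigs were higher with PhenDC3, with 118 of 153 features higher and 12 lower (118 and 12 adjusted over the list alone), a median of 1.56 and a camera adjusted p of 7.89e-27. With an estimated correlation it held at 0.00177, the highest over 13 camera alternatives (lowest 9.78e-28). All 17 BES1 features before the last and all 60 block features were higher by at least 2-fold. The blocks were found from falls with BMH-21, so higher values with PhenDC3 than with BMH-21 were partly selected for there. Short features were lower (365 of 1165, with 120 higher, or 343 and 106 adjusted over the list alone), with a median of -0.14 and an adjusted p of 0.00431. That call did not hold with an estimated correlation (0.182, the highest over 13 camera alternatives, lowest 0.00111). The arm and unitig, start proximal, end proximal and long lists did not pass (adjusted p = 0.943, 0.398, 0.943 and 0.943), and their medians of -0.05, -0.05, -0.02 and -0.02 stood beside means of 0.12, 0.02, 0.06 and 0.05. Fry called the end proximal features higher (adjusted p = 0.0265).

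PhenDC3 and CX-5461 differed in 5565 features, 2847 higher and 2718 lower with PhenDC3, and 443 by at least 2-fold, of which 382 were higher. On expression site contigs 127 of 153 features were higher with PhenDC3 and 0 lower by edgeR (128 and 0 adjusted over the list alone), with a median of 1.55 and a camera adjusted p of 5.88e-40. It held with an estimated correlation (0.000284, the highest over 13 camera alternatives, lowest 9.91e-42). Short features were lower, with 354 of 1165 lower and 82 higher (333 and 77 adjusted over the list alone), a median of -0.16 and an adjusted p of 4.76e-05. With an estimated correlation the adjusted p was 0.0478, the highest over 13 camera alternatives (lowest 1.97e-05), but 6 of the 35 divisions of the 8 libraries into groups of 4 gave an unadjusted p as small as the real one, so chance cannot be excluded. The other 4 lists did not pass (adjusted p = 0.818 each), and the arm and unitig, start proximal and end proximal medians of -0.01, -0.02 and -0.02 stood beside means of 0.13, 0.04 and 0.03. Fry called the long features higher (adjusted p = 0.0174).

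The 10 most abundant features took 10.3% ± 0.143 of control counts and 7.36% ± 0.241, 7.39% ± 0.315 and 8.49% ± 0.356 with BMH-21, CX-5461 and PhenDC3 (SD, n = 4 each, exact permutation p = 0.0286 for each, adjusted p = 0.0312), lower in 4 of 4 libraries of each compound. The last BES1 feature, the most abundant of all, accounted for most of these falls.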

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

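The tests of explanations in this part, and the splits for BMH-21 against control, were chosen only after the result was seen; the other splits of the libraries were fixed earlier. In control replicate 1, Tb427_100015200 lay at 253 CPM, far from the 310.1 to 315.8 CPM of the other controls: its gap was 0.909 of the range. Of 72 groups examined in this way 1 was out of line, where chance gives about 3.6. Without control replicate 1 or any other replicate, the log2 fold change of this feature with CX-5461 stayed between 1.10 and 1.21. Compared over all features with enough counts, control replicate 1 stood apart from the other controls. The chi-square per degree of freedom of its pairs was 6.72 to 7.53, beside 2.69 to 2.92 for pairs of the others. Pairs within the compound groups ran from 2.9 to 9.66.

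For each comparison, the 8 libraries were divided in all 35 ways into groups of 4. The real division called more features than every other one. This is 1 of 35 for each comparison, the smallest share these divisions can give, which makes chance unlikely for the number of features called. Against control, the numbers were 1885 against at most 1 for BMH-21, 3493 against 2 for CX-5461 and 6117 against 330 for PhenDC3. Between compounds, they were 1889 against 105 for CX-5461 and BMH-21, 6288 against 1 for PhenDC3 and BMH-21, and 5565 against 2 for PhenDC3 and CX-5461. Chance cannot be excluded for the number of lists past the threshold in the 5 comparisons where any passed. Divisions that mix the groups unequally keep part of the difference between them, so these counts are not a pure measure of chance. As many lists passed in 24 of 35 divisions for BMH-21 and control (2, highest other 5), 26 for CX-5461 and control (2, highest other 4), 20 for PhenDC3 and control (2, highest other 6), 23 for PhenDC3 and BMH-21 (2, highest other 4) and 27 for PhenDC3 and CX-5461 (2, highest other 5). For CX-5461 and BMH-21 the real number was 0 (highest other 5), which all 35 divisions reach whatever the data, so the count tells nothing there. The expression site list alone had its smallest p in the real division for BMH-21 (2.59e-83, smallest other 6.15e-26) and CX-5461 (5.21e-67, smallest other 7.03e-26). The arm and unitig list had a p as small in 5, 8 and 15 of 35 divisions for BMH-21, CX-5461 and PhenDC3 against control, and the short list in 10 for PhenDC3 and control and 10 for PhenDC3 and BMH-21, so chance cannot be excluded for these calls.

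The fall along BES1 with BMH-21 and CX-5461 was set against the scaling of the libraries: the median of the 17 features before the last was at most -2.55 under 4 scalings with both compounds, which argues against library composition as the whole cause. Coding length and abundance do not account for the order up to the last feature: the rank correlation of fold change and position, given both, was -0.95 and -0.92 over the 17 features and at most -0.89 with any 1 left out, and over all 18, which include the last feature, it went only from -0.60 and -0.61 to -0.55 and -0.56 (-0.45 at the weakest with 1 left out). The last feature fell by less than every feature before it, by a gap of at least 0.24. This is in line with slow loss of its mRNA after transcription slows, but a single time point cannot tell that from continued transcription of that feature. A loss of polymerase I transcription, named for both compounds as background, stays open as untested, since no precursor RNA was measured.

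Falls on the other 12 expression site contigs may come from reads shared with BES1 copies. Among the 97 features with a BES1 feature of like length (within 1%), fold changes followed those of that feature, with a rank correlation of at least 0.60 for both compounds. Of the other 38 features, 26 fell with BMH-21 and 27 with CX-5461, with a median of -1.03 or lower; these cannot be told apart from copies, since length stands in for sequence here. A change of these sites with the compounds stays open.

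The fall of the repeated blocks was set against a single change in the carry-over of RNA without poly(A) tails. With BMH-21 the medians of the middle and the first part differed by -2.33, which argues against one common factor. The middle part was the one picked for its fall with BMH-21, which may widen this gap. With CX-5461 the medians differed by -0.08, so there such a factor cannot be told apart from other causes, as every part fell alike. Reads moved among copies do not account for the fall, since the log2 ratio of the summed share to control was -2.54 or lower with both compounds. The layout of the blocks resembles ribosomal RNA genes, and less ribosomal RNA made may underlie the fall. At least 59 of 60 features fell with each compound, but the blocks were found from features that fell with BMH-21. That count therefore gives no support, and the table has no names to test the idea, so it stays a hypothesis.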

How the results depend on the processing

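The alternatives on core contigs alone, on TMM factors without the expression sites, and for the medians and added shares were chosen only after the result was seen. Of 837 values under alternatives, 786 stayed within 1.5 times a count, on the same side of a test or within the replicate spread, and 51 moved; none changed sign. All 156 values of the named features kept their call.

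Requiring an adjusted p under 0.01 left 1040 features for BMH-21 and control, 2224 for CX-5461 and control and 1129 for CX-5461 and BMH-21. Requiring a 2-fold change left 277, 318, 235, 50, 511 and 443 in the order of the report, since most changes were smaller. With library size only, the calls shifted towards rises: 74.5% in place of 49.5% for BMH-21 and control, 74.9% in place of 45.5% for CX-5461, 64.7% in place of 48.8% for PhenDC3, and 59% in place of 39.1% for CX-5461 and BMH-21. Medians over all features then lay at 0.057, 0.092, 0.076 and 0.038.

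The number of lists past the threshold also moved. An estimated correlation left 1, 1 and 0 for BMH-21, CX-5461 and PhenDC3 against control and 1 for PhenDC3 and BMH-21. Core contigs alone, where the expression site and subtelomere lists drop out by construction, gave 0, 1 and 1 against control and 1 for each of PhenDC3 and BMH-21 and PhenDC3 and CX-5461. Fry gave 5 for CX-5461 and 4 for PhenDC3 against control, library size only gave 2 for CX-5461 and BMH-21, and no filter on low counts gave 0 for PhenDC3 and control. Leaving out single replicates gave 2 to 4 for PhenDC3 and control, with 4 without control replicate 1. The cause was not tested, except where named.

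With the controls split 2 and 2, shared calls in the same direction went from 1234 to 694.5 for BMH-21 and CX-5461, from 771 to 414 for BMH-21 and PhenDC3 and from 2151 to 1397 for CX-5461 and PhenDC3, with fewer libraries per test. Leaving out single replicates, called features ranged from 1466 to 2111 for BMH-21, 3003 to 3382 for CX-5461 and 5685 to 6057 for PhenDC3 against control.

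The replicate numbers do not pair the libraries: 1 of 24 pairs with the same number had correlated deviations over 0.1, and in 7 of the 24 the correlation was highest for the shared number. With the replicate number as a replicate block, edgeR called 1901, 3508, 6140, 1939, 6304 and 5578 features, and the expression site list passed for PhenDC3 and control.

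Shares and TMM factors by VSG, ESAG, ribosomal protein or non-coding annotation were not run, as the table names no genes. The filter on low counts left 6464 features untested, 2822 of them without a count in any library.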

Other observations

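The tests in this part were chosen only after the result was seen. Features that rose at least 2-fold with PhenDC3 on core contigs lay next to one another more often than chance: 3 adjacent pairs on one strand among 60 features, where random draws gave 0.4 on average (permutation p = 0.00756). The same test gave 4 pairs among the 13 rises with CX-5461 (permutation p = 1e-05, the smallest it can give) and 1 among the 11 with BMH-21 (permutation p = 0.0127). Falls gave 14 pairs among 31 with BMH-21 and 15 among 32 with CX-5461 (permutation p = 1e-05 each), repeated blocks included. Adjacent features may thus change together, though tandem copies that share reads would give the same. The 22 core features that fell at least 2-fold with PhenDC3 gave 0 such pairs.

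A shift of features near transcription starts with PhenDC3 was tested on core contigs alone, which leaves out the subtelomeres. The 443 start proximal features had a median of 0.01, against 0.02 for the others. The 95% interval of the difference ran from -0.037 to 0.031, within 0.1 on either side. Features are not independent replicates, and the interval may leave out the spread between libraries. It therefore describes these medians and does not exclude a shift.

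On core contigs, log2 fold changes with PhenDC3 fell with abundance in control: the most abundant 10% had a median of -0.26 (quartiles -0.40 and -0.06) and the least abundant 10% one of 0.06, with a rank correlation of -0.25 across features. With CX-5461 the correlation was -0.18, and with BMH-21 it was 0.06. Short features on core contigs were lower with PhenDC3 (median -0.07, camera adjusted p = 0.0116) and higher with CX-5461 (median 0.11, camera adjusted p = 0.00883), and neither call held with an estimated correlation (0.409 and 0.376).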
